A study of Arabidopsis thaliana with 8 samples.

How the data were processed

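The material was 13-day-old Arabidopsis thaliana seedlings of wild type (Col-0) and of skip-1, each given 0 or 100 µM abscisic acid (ABA) for 3 h. Each of the 4 groups had 2 libraries, made from RNA isolated with RNAiso Plus and an NEBNext Ultra RNA kit. The labels number the replicates 1 and 2 in each group and do not say that equal numbers were handled together. The deviations of replicate 1 from its group mean correlated at 0.111 to 0.258 in all 6 pairs of groups. With 2 libraries per group, replicate 2 deviates as the mirror of replicate 1, so the signs are not independent and arbitrary numbering could also give them. These values therefore cannot show whether equal numbers form pairs. The main fit has no block, and the value with the replicate number as a block is given beside each result whose call it changes. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these libraries. The libraries held 20870110 to 23640113 counted reads.

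The deposited table used here holds raw read counts per gene for all 8 libraries. A companion table by the authors holds FPKM, fragments per kilobase of gene scaled to the counted reads of the library. Each FPKM value was checked against the counts and equals the count divided by a gene length and by the column total, so it is scaled by library size only. Per the submitters' processing notes, the reads were handled with Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1 on the TAIR10 genome. The role of each tool, the options, the strand setting and the annotation release are not given in the sources used here. The authors added 72 unannotated features to the table, and the assembler is not given in the sources used here. Without a known strand setting, counts of genes that overlap on opposite strands are uncertain. Reads shared between close paralogs, such as light-harvesting, Rubisco small subunit, small heat shock protein and IMA genes, could not be assigned from gene counts. Raw reads were not analysed here, so splicing was not measured.

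Gene symbols, positions and intron numbers came from the RefSeq annotation of TAIR10.1, which matched 32835 of the 33674 features. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the tool's expression filter applied by group, which left 21008 features, 63 of them unannotated. Libraries were scaled by trimmed mean of M values (TMM). A robust quasi-likelihood model with 1 coefficient per group had 4 residual degrees of freedom, a common dispersion of 0.0178 and a median of 4.64 prior degrees of freedom. The tests were quasi-likelihood F tests, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. The comparisons were ABA in wild type, ABA in skip-1, skip-1 against wild type without ABA, the same with ABA, and the difference between both ABA effects (the interaction). Fold changes are on the log2 scale and carry the tool's default prior count. Their standard error (SE) was derived as the absolute log2 fold change divided by the square root of the F statistic. It is therefore approximate, most of all for genes with few counts. A prior count of 2 was used for log2 normalised counts (CPM, counts scaled to library size). CPM values use the TMM-scaled library sizes.

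Named genes were chosen by a rule. SKIP came first. In each comparison the 8 largest increases and the 8 largest decreases followed, among genes past the threshold with a mean log2 CPM of at least 2. In the comparisons of a pair of groups, both libraries of 1 group also had to lie above both of the other. From each gene list, up to 4 members with the smallest adjusted p were named in each comparison. Where few members of a list moved, or some moved against the rest, further members were named, such as PYL7, FLM, FUL and LSM4, and these were chosen after their values were seen. Where a group had no count for a gene, the fold is a lower bound computed with a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with its 95% counting interval, since the fitted value of such a gene depends on the prior count. Intervals and floors cover counting error only.

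There were 21 lists with 308 genes in all, written from general knowledge of the species. They were ABA receptors, clade A PP2C phosphatases, SnRK2 kinases, ABA transcription factors, ABA- and dehydration-induced genes, ABA metabolism, circadian clock, flowering time, SR splicing factors, other spliceosome components, light harvesting with Rubisco small subunit, jasmonate and wounding, salicylate and defence, heat shock, Aux/IAA auxin response, flavonoid and anthocyanin, cell division, root markers, guard cell and stomatal lineage markers, seed storage and oil body markers, and floral organ markers. A list was tested if at least 3 members were measured, which left 19. Each list was compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. The test was repeated with a correlation estimated from the residuals of the fit. With 4 residual degrees of freedom that version is expected to have little power, which was not simulated, so a list that misses its threshold may still have moved. Where the genes of a list correlate above the preset, the preset version gives p-values that are too small. The rotation test fry asked whether a list's genes moved, on balance, 1 way. It does not compare the list with other genes.

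The size of the ABA response was compared between genotypes over the genes called for the mean of both ABA effects, split by direction, with fry on the interaction, adjusted over both directions. The comparisons, tests, lists, the rule for named genes and the alternatives were fixed before the data were examined. A list of iron-deficiency genes and a split of genes by intron number were chosen after results had been seen, and their tests were adjusted over the comparisons and sets run.

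The alternatives were DESeq2 size factors or library size alone in place of TMM, no count filter, at least 10 counts in every library, the DESeq2 1.42.0 Wald test, a fit of only the groups compared, a replicate number as a block, a minimum 2-fold change, and limma on log2 FPKM with pseudocounts of 1 and 0.1 and with or without a minimum mean FPKM of 1. Each library was also left out in turn. The lone library of its group was then assumed to vary like those of the other groups. Such a fit has less power, so a lost call does not by itself show that the effect rested on the library left out.

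The pipeline was tested on simulated data made from these counts. In a simulated comparison of a pair of groups, edgeR recovered 19.4% of 1.5-fold, 58.2% of 2-fold and 97% of 4-fold changes, with 11 false calls among 127. For a simulated interaction it recovered 1.5%, 13.4% and 89.4%, with 7 false calls among 76. Of 100 unchanged lists, camera gave p under 0.05 for 2 and fry for 9, and both found 10 of 10 raised lists, drawn from 1 pool of raised genes. Genes were simulated independently of each other, so this is no check of the preset correlation against that in the data. Few genes were changed, so recovery and false calls may differ in comparisons where many genes moved. Groups of 2 libraries are too small for a test of single deviating libraries or of regrouped samples, and neither was done.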

Results

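Transcript levels were measured by RNA sequencing in 13-day-old seedlings of wild type and of skip-1, a mutant of SKIP, which codes for a splicing factor that also acts in transcription. Seedlings had received 0 or 100 µM abscisic acid (ABA), a hormone of drought stress and seed dormancy, for 3 h. Each of the 4 groups held 2 libraries. The library totals were 22659593 and 23602532 counted reads in wild type without ABA, and 22258628 and 20870110 with ABA. They were 23640113 and 21121411 in skip-1 without ABA, and 21654833 and 22017597 with ABA. Of 33674 features, 7972 had no count in any library and 21008 were tested. Across genes, which are not independent replicates, log2 normalised counts (CPM, counts scaled to library size) correlated at 0.983 or more between libraries of 1 group and at 0.959 or less between groups. The first principal component, with 60.2% of the variance, separated the libraries with ABA from those without, and the second, with 25.5%, separated the genotypes. Levels are given as CPM, mean ± SD with n = 2, and changes as log2 fold changes ± an approximate SE derived from the F test. The study's title names ABA-dependent splicing, which counts per gene do not measure.

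SKIP itself (AT1G77180, TAIR10.1 chromosome 1, 28999577 to 29002143, minus strand, at most 3 exons) was measured first. Its level was 157 ± 8.85 CPM in wild type without ABA and 148 ± 18.1 CPM with ABA. In skip-1 it was 119 ± 20.7 CPM without ABA and 117 ± 11.9 CPM with ABA. The difference between genotypes was −0.40 ± 0.15 without ABA (adjusted p = 0.0822) and −0.35 ± 0.15 with ABA (adjusted p = 0.1), so neither passed the threshold. With the replicate number as a block in the fit (the replicate block), both passed (edgeR adjusted p = 0.0104 and 0.0152). ABA did not change SKIP past the threshold in wild type (−0.08 ± 0.14, adjusted p = 0.697) or in skip-1 (−0.03 ± 0.15, adjusted p = 0.913). The lesion in skip-1 is not given in the sources used here, so this level is no check of the genotype labels.

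The comparison of wild type with and without ABA asked which transcripts 3 h of the hormone changed. Among the largest increases were 4 genes of late embryogenesis abundant (LEA) proteins, which protect drying cells. AT3G17520 rose from 0.186 ± 0.148 to 335 ± 4.17 CPM (10.78 ± 0.27, adjusted p = 1.15e-07), and LEA7 (AT1G52690) from 0.742 ± 0.419 to 756 ± 95 CPM (9.99 ± 0.46, adjusted p = 6.76e-06). EM1 (AT3G51810) and the gibberellin-regulated gene GASA3 (AT4G09600) had no count without ABA and were at least 234-fold and at least 134-fold higher with it. From 1 or 2 counts, the LEA gene AT2G42560 rose 1640-fold (95% counting interval 294 to 64900), the phosphatase gene HAI3 (AT2G29380) 1320-fold (364 to 10900) and the acetyltransferase gene NATA1 (AT2G39030) 1060-fold (292 to 8720). CSLG2 (AT4G24000), a cellulose synthase-like gene, rose by 9.72 ± 0.40. The largest decreases were those of the receptor kinase gene CRK30 (AT4G11460), 321-fold (110 to 1560), and of the iron transporter gene IRT1 (AT4G19690), 316-fold (56.5 to 12500), to 3 and 1 counts. The expansin gene EXPA8 (AT2G40610) changed by −6.98 ± 0.28, and PYL6 (AT2G40330), an ABA receptor, went from 27.3 ± 2.82 to 0.328 ± 0.0952 CPM (−6.35 ± 0.35). The cell wall enzyme gene XTH15 (AT4G14130), the receptor gene PYL4 (AT2G38310), the RING protein gene AT3G20395 and the methyltransferase gene AT1G15125 followed, with −5.21, −4.95, −4.78 and −4.72. In all, edgeR called 9061 of 21008 genes (43.1%), 4974 higher and 4087 lower, and 4321 of them changed at least 2-fold. Higher genes were 54.9% of the calls with TMM and 36% with scaling by library size alone, which moved the median of all genes from −0.011 to −0.219.

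ABA- and dehydration-induced genes and PP2C phosphatases had the smallest adjusted p among the lists in wild type. All 29 ABA- and dehydration-induced genes rose (29 adjusted over the list alone), with a median of 5.14, also with EM1 at its bound (adjusted p = 1.16e-69). KIN1 rose by 7.01 ± 0.22, RAB18 by 5.59 ± 0.14, LTI30 by 5.34 ± 0.13 and the transcription factor gene HB7 by 5.22 ± 0.15. All 9 clade A PP2C phosphatases, which repress the ABA kinases, rose (9 adjusted over the list alone; median 4.89, also with AHG1 at its bound; adjusted p = 2.37e-22). ABI2 went from 10.5 ± 0.914 to 310 ± 13.8 CPM and HAB1 from 24.6 ± 5.74 to 634 ± 73.3 CPM. Of 13 genes of ABA metabolism, 10 rose and none fell (10 adjusted over the list alone; median 1.92, adjusted p = 1.4e-08). They included genes of hormone breakdown, CYP707A1 (5.54 ± 0.13) and CYP707A4 (4.0 ± 0.29), and of synthesis, AAO3 (1.92 ± 0.13) and ABA3 (1.28 ± 0.13). These 3 list calls held with an estimated correlation, although with the replicate block that of the ABA- and dehydration-induced genes did not (adjusted p = 0.0679). All 5 ABA transcription factors rose (5 adjusted over the list alone), among them ABF3 (3.82 ± 0.16) and ABI5 (3.13 ± 0.20), with a median of 2.88 (adjusted p = 4.95e-08, and adjusted p = 0.114 with an estimated correlation). Of 9 ABA receptors, 6 fell and 1, PYL7, rose by 1.15 (7 adjusted over the list alone). Their median was −1.89 (adjusted p = 4.99e-06, and adjusted p = 0.163 with an estimated correlation), with PYR1 at −1.89 and PYL8 at −2.06. The SnRK2 kinases went both ways, 4 higher and 3 lower of 10 (7 adjusted over the list alone; median 0.24, adjusted p = 0.57), with OST1, the main stomatal kinase, at 1.98 ± 0.11 and SNRK2.5 at −2.58.

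Lists outside ABA signalling also moved in wild type. Of 10 heat shock genes, 9 rose and none fell (9 adjusted over the list alone; median 4.64, adjusted p = 1.04e-07), a call that held with an estimated correlation. HSP22 rose by 5.27 ± 0.30, HSP70 by 4.30 ± 0.38, and HSP17.4 from 1 count by 643-fold (115 to 25400). Of 16 jasmonate and wounding genes, 14 rose and none fell (15 adjusted over the list alone; median 2.07, adjusted p = 2e-06, and adjusted p = 0.22 with an estimated correlation). VSP2, a storage protein gene of the wound response, rose by 4.96 and the repressor gene JAZ1 by 3.95. Of 21 genes for light harvesting and the Rubisco small subunit, 15 fell and none rose (15 adjusted over the list alone; median −0.82, adjusted p = 1.68e-06, and adjusted p = 0.322 with an estimated correlation). LHCB1.4 changed by −2.22 ± 0.18, RBCS1B by −1.59 ± 0.13 and LHCB4.2 from 817 ± 63.3 to 308 ± 24.9 CPM. The share of counts on chloroplast genes was 0.701% and 0.642% without ABA, and 0.544% and 0.551% with ABA. Of 19 root markers, 11 fell, with CASP2 at −2.63, and 3 rose, WOX5 (1.55), SULTR1;2 (0.97) and TIP2;3 (0.73), with 14 called when adjusted over the list alone. SULTR1;2 and TIP2;3 lost their calls without wild type mock replicate 2, either wild type ABA library or skip-1 mock replicate 1, and SULTR1;2 also without skip-1 mock replicate 2 (adjusted p up to 0.204 and 0.229), and SULTR1;2 also with the replicate block (0.0573). Their median was −0.77 (adjusted p = 0.0362, and adjusted p = 0.593 with an estimated correlation). That list's call was lost without wild type ABA replicate 1 (adjusted p = 0.0531) or 2 (0.0554) or wild type mock replicate 1 (0.0625). In the flowering time list only SOC1, an inducer of flowering (2.36 ± 0.11), and FUL (1.96) rose, and its median of −0.17 differed in sign from its mean of 0.34 and from camera's direction (adjusted p = 0.571).

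The same treatment was compared in skip-1, to ask how the mutant responded to ABA. EM1 had no count without ABA and was at least 127-fold higher with it, and BSMT1 (AT3G11480), a salicylate methyltransferase gene, rose 1400-fold from 1 count (251 to 55300). AT3G17520 went from 0.419 ± 0.139 to 141 ± 11.1 CPM (8.40 ± 0.24), and LEA7 from 0.946 ± 0.658 to 353 ± 64.5 CPM (8.58 ± 0.44). NATA1 rose by 8.31 ± 0.66, the kinase gene AT5G24080 by 7.80 ± 0.25, the LEA gene EM6 (AT2G40170) 294-fold (100 to 1430) and AT2G42560 221-fold (60.9 to 1830). EXPA8 (−5.78 ± 0.22), CRK30 (−4.79 ± 0.51) and PYL6 (−4.18 ± 0.32) led the decreases. They were followed by the acyltransferase gene AT4G15390 (−3.52), the glucosyltransferase gene UGT72E1 (AT3G50740, −3.46), AT1G19960 (−3.40), the ammonium transporter gene AMT1;3 (AT3G24300, −3.37) and AT2G22122 (−3.32). In all, 5978 genes (28.5%) were called, 3429 higher and 2549 lower, and 2516 changed at least 2-fold. Without skip-1 ABA replicate 1 or 2, 3892 and 3532 genes were called. Of the genes called higher, 2899 were also higher in wild type, where 812 would be shared if the calls were independent, and 7 were lower in wild type. Of those called lower, 1904 were shared (496 if independent) and 9 were higher in wild type. Over all tested genes, the ABA effects of both genotypes correlated at r = 0.832 and rho = 0.757, and 77.9% had the same sign.

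The lists that passed in both genotypes moved in the same directions. All 29 ABA- and dehydration-induced genes rose (29 adjusted over the list alone; median 4.07, also with EM1 at its bound; adjusted p = 8.3e-92), with KIN1 at 6.54, COR15A at 5.89 and RAB18 at 4.92. All 9 PP2C phosphatases rose (9 adjusted over the list alone; median 3.55, adjusted p = 1.18e-24), with ABI2 going from 18.3 ± 2.01 to 214 ± 49.2 CPM. Of the genes of ABA metabolism, 10 of 13 rose (11 adjusted over the list alone; median 1.70, adjusted p = 3.69e-13), and of the heat shock genes 7 of 10 (9 adjusted over the list alone; median 2.67, adjusted p = 1.15e-05), with HSP22 at 4.95 ± 0.42. These 4 calls held with an estimated correlation. Of 16 jasmonate and wounding genes, 14 rose (14 adjusted over the list alone; median 2.46, adjusted p = 1.22e-15, and adjusted p = 0.0936 with an estimated correlation), with VSP1 at 3.90 and the jasmonate synthesis gene OPR3 at 2.21. All 5 ABA transcription factors rose (5 adjusted over the list alone; median 2.06, adjusted p = 1.68e-08, and adjusted p = 0.0969 with an estimated correlation), with ABF3 at 2.59 ± 0.15. Of 21 light-harvesting and Rubisco genes, 13 fell (15 adjusted over the list alone; median −0.74, adjusted p = 4.85e-07, and adjusted p = 0.308 with an estimated correlation), with RBCS1B at −1.39 and LHCB4.2 at −1.1. Of the 21, 20 were called lower with the replicate block. Of 9 receptors, 6 fell and PYL7 rose by 1.1 (8 adjusted over the list alone; median −1.09, adjusted p = 1.81e-05, and adjusted p = 0.153 with an estimated correlation), with PYL4 at −2.94. Median, mean and test differed in sign for the SnRK2 kinases (median −0.04, mean 0.34), salicylate genes (−0.02, 0.30), Aux/IAA genes (−0.18, mean 0.03 with camera downward) and SR splicing factors (0.02, mean 0.07 with camera downward). None of these 4 lists passed the threshold.

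Skip-1 was then compared with wild type without ABA, to ask how the mutant differed before any hormone was given. As skip-1 was the only mutant line, other differences between this line and Col-0 cannot be told apart from the mutation. Among the largest increases was a regulator of iron uptake. The transcription factor gene bHLH38 (AT3G56970), induced by iron deficiency, rose from 2.13 ± 1.81 to 197 ± 57.2 CPM (6.53 ± 0.55, adjusted p = 0.00129). The cupin gene AT4G36700 rose by 6.95 ± 0.42 (adjusted p = 0.000179) and Novel00018, an unannotated feature of the authors' table, by 6.52 ± 0.51 (adjusted p = 0.000349). GASA3 had no count in wild type and was at least 12-fold higher in skip-1, where its fitted change of 7.04 depends on the prior count. The largest decrease was that of the pseudogene AT4G04410, from 26.8 ± 1.41 to 0.586 ± 0.0357 CPM (−5.50 ± 0.18, adjusted p = 7.55e-06). MLP329 went from 80.4 ± 5.29 to 6.99 ± 1.62 CPM (−3.53 ± 0.18). The defensin-like gene AT3G59930 (−3.89 ± 0.41), the protease gene AT5G48430 (−3.43 ± 0.23), the receptor kinase gene CRK28 (−3.17 ± 0.25) and the glutaredoxin-like gene AT4G15690 (−3.02 ± 0.24) also fell. Another 6 of the 16 genes lost their call when 1 library was left out. DFR (AT5G42800, 7.19 ± 1.78) of anthocyanin synthesis was at 0.331 ± 0.354 in wild type and 48.5 ± 61.7 CPM in skip-1, and kept its call only without skip-1 mock replicate 2 (adjusted p = 0.0385 with all libraries, 0.206 without wild type mock replicate 2, 0.0678 with the replicate block). NUDT24 (7.09 ± 1.27), the defensin-like pseudogene AT2G16367 (6.76 ± 1.16) and THA1 (−3.11 ± 0.63) lost it without either wild type mock library, with adjusted p up to 0.102, 0.0805 and 0.0841. The defensin-like gene AT1G13609 (5.95 ± 0.98) lost it without skip-1 mock replicate 1 (0.0607). The pseudogene AT1G69140 (−3.19 ± 0.65) lost it without wild type mock replicate 1 or either skip-1 mock library (up to 0.0876).

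In total 4297 genes (20.5%) differed between skip-1 and wild type without ABA, 2195 higher and 2102 lower, and 1584 differed at least 2-fold. Without wild type mock replicate 1 or 2, 1996 and 1383 genes were called, and without skip-1 mock replicate 1, 2441. Among the planned lists, photosynthesis genes had the smallest adjusted p by camera, with 15 of 21 light-harvesting and Rubisco genes higher and only RBCS1B lower (−0.74; 16 adjusted over the list alone). With the replicate block RBCS2B was lower too (0.0386). LHCB4.2 went from 817 ± 63.3 to 2420 ± 37.1 CPM (1.57 ± 0.12), and LHCA4 rose by 1.67 ± 0.20. The list's median was 1.00 (adjusted p = 8.3e-11, and adjusted p = 0.316 with an estimated correlation). The chloroplast share of counts was 0.883% and 0.948% in skip-1, higher than in wild type. Of 14 salicylate and defence genes, 6 rose and none fell (7 adjusted over the list alone; median 1.01, adjusted p = 0.000192, and adjusted p = 0.316 with an estimated correlation). PR2 (AT3G57260), a glucanase gene of the defence response, rose by 4.74 ± 0.45, and ICS1, of salicylate synthesis, by 1.16 ± 0.13. The other 4 lost their calls, SARD1 without wild type mock replicate 1 (0.052), WRKY40 without either wild type mock library (up to 0.12), WRKY70 without any 1 mock library (up to 0.125), and PR1 without wild type or skip-1 mock replicate 2 or either skip-1 ABA library (up to 0.092), and with the replicate block (0.0599). Of 16 jasmonate and wounding genes, 6 rose and none fell, with JAZ6 at 1.3 ± 0.18 (9 adjusted over the list alone; median 0.99, adjusted p = 0.000192, and adjusted p = 0.371 with an estimated correlation). Of the 6, JAZ6 alone kept its call without each library. AOS lost it without either wild type mock library or skip-1 mock replicate 1, VSP2 without wild type mock replicate 2 or skip-1 mock replicate 1, and JAZ5 without wild type mock replicate 2 or either skip-1 mock library (up to 0.118, 0.0984 and 0.105). JAZ8 kept it only without skip-1 mock replicate 1 and LOX2 only without wild type mock replicate 1 (up to 0.188 and 0.177), and LOX2 lost it with the replicate block (0.0706).

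In the flowering time list, FLC (AT5G10140), a repressor of flowering, fell from 2.27 ± 0.51 to 0.134 ± 0.0763 CPM (−4.07 ± 0.48). At so low a level the size of this change is uncertain. Its relatives MAF2 (−1.07), MAF5 (−1.77) and FLM (−0.73) were lower too. FT (AT1G65480), the flowering signal that FLC represses, fell as well (−1.91 ± 0.21), while the inducers SOC1 (0.60) and FUL (1.16) rose. That made 5 lower and 2 higher of 13 (9 adjusted over the list alone; median −0.73, adjusted p = 0.0288, and adjusted p = 0.316 with an estimated correlation). The list's call was lost without skip-1 mock replicate 2 (0.0741), and that of SOC1 without either wild type mock library (up to 0.0515). MAF5 lost its call without wild type mock replicate 1 or skip-1 mock replicate 1 (up to 0.0561), FLM without either wild type mock library or skip-1 mock replicate 2 (up to 0.0907), and FUL without any 1 of the 8 libraries (up to 0.187).

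ABA genes differed between the genotypes before any hormone was given. Of 9 PP2C phosphatases, 5 rose (7 adjusted over the list alone; median 0.82, or 0.80 with AHG1 at its bound; adjusted p = 0.00107, and adjusted p = 0.371 with an estimated correlation), with PP2CA going from 37.3 ± 8.96 to 91.3 ± 20.6 CPM (1.29 ± 0.23). The other 4 lost their calls, HAB2 without wild type mock replicate 2 (0.0647), ABI2 without either wild type mock library or skip-1 mock replicate 1 (up to 0.0904), ABI1 without either wild type mock library or skip-1 mock replicate 2 (up to 0.107), and HAI2 without these or either wild type ABA library (up to 0.14). Of 13 genes of ABA metabolism, 5 rose, among them the synthesis genes ABA1 (1.92 ± 0.24) and ABA2 (1.23 ± 0.17) and BGLU18 (1.48 ± 0.15), whose enzyme frees stored ABA. The breakdown genes CYP707A1 (0.84 ± 0.12) and CYP707A2 (2.09 ± 0.38) rose as well, CYP707A2 losing its call without either wild type mock library or skip-1 mock replicate 1 (adjusted p up to 0.0822). Only AAO3 fell (−0.71, lost without wild type mock replicate 1, adjusted p = 0.0555). There 7 were called when adjusted over the list alone (median 0.84, adjusted p = 0.00107, and adjusted p = 0.316 with an estimated correlation). Of 9 receptors, PYL6, PYL4 and PYR1 fell (6 adjusted over the list alone; median −0.54, adjusted p = 0.00713, and adjusted p = 0.382 with an estimated correlation), and all 3 lost their calls without wild type mock replicate 2 (adjusted p = 0.053, 0.0609 and 0.0513). With the replicate block 5 receptors were lower, PYL1 (0.0377) and PYL8 (0.0326) among them. The ABA- and dehydration-induced genes split, 5 higher and 3 lower of 29 (9 adjusted over the list alone; median 0.08, also with EM1 at its bound; adjusted p = 0.192). The list passed without skip-1 mock replicate 1 (5.11e-05). P5CS1, for proline synthesis (2.06 ± 0.27), GOLS2 (2.00 ± 0.17) and HB7 (1.52 ± 0.13) rose, while LEA14 (−0.67), COR15B (−1.03) and LTI30 (−0.60) fell. These 3 decreases lost their calls without skip-1 mock replicate 1 and wild type mock replicate 1 (LEA14, up to 0.0783), without skip-1 mock replicate 1 and wild type mock replicate 2 (COR15B, up to 0.0882) and without wild type mock replicate 2 (LTI30, 0.0611), each left out singly. Flavonoid and anthocyanin genes had 3 of 14 higher, CHI (0.93 ± 0.13), TT8 and DFR (7 adjusted over the list alone; median 1.86, adjusted p = 0.00713, and adjusted p = 0.781 with an estimated correlation). That call was lost without skip-1 mock replicate 1 (0.198), and TT8's without wild type mock replicate 2 (0.0621).

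Among splicing genes, 4 of 20 SR splicing factors rose (4 adjusted over the list alone; median 0.15, adjusted p = 0.167), with RSZ22a at 0.61 ± 0.09. Only RSZ22a kept its call without each library. RSZ33 lost it without either wild type mock library or skip-1 mock replicate 2, SCL33 without either wild type mock library or skip-1 mock replicate 1, and RSZ32 without any 1 of the 8 (adjusted p up to 0.115, 0.122 and 0.217). Of 20 other spliceosome components 2 rose, RDM16 (0.92 ± 0.10) and STA1 (0.73), and 2 fell, GRP8 (−0.53) and LSM4 (−0.31; 4 adjusted over the list alone; median 0.04, adjusted p = 0.793). RDM16 kept its call without each library, STA1 lost it without either wild type mock library (up to 0.0565), GRP8 without any mock or skip-1 ABA library (up to 0.184) and LSM4 without any 1 of the 8 (up to 0.16). Of 22 circadian clock genes, 6 rose and 4 fell (14 adjusted over the list alone; median 0.33, adjusted p = 0.238). The list passed with the replicate block (0.0245), where 11 members were higher and 5 lower. CCA1 (4.68 ± 0.78), PRR9 (4.68 ± 0.94), RVE8 (3.27 ± 0.65) and LHY (2.65 ± 0.45) rose, and PRR3 (−1.67 ± 0.20) and ELF3 (−0.62) fell. The calls of PRR3 and ELF3 alone held without each library. LHY lost its call without wild type mock replicate 2 (0.0592), CCA1 and RVE8 without either wild type mock library (up to 0.0873 and 0.105), and PRR9 without these or skip-1 mock replicate 1 (up to 0.124). No cell division gene of 12 was called (median 0.26, adjusted p = 0.192), until skip-1 mock replicate 2 was left out (0.0371 for the list), or, for KNOLLE, until the replicate block was added (0.0166). The seed storage list, with 1 measured gene, and the floral list, with 2, were not tested. In the medians, the SnRK2 kinases (−0.16, mean 0.03), heat shock genes (−0.29, mean 0.43) and root markers (−0.08, mean 0.02) differed in sign from their means, and camera followed the medians.

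**Figure D1:**
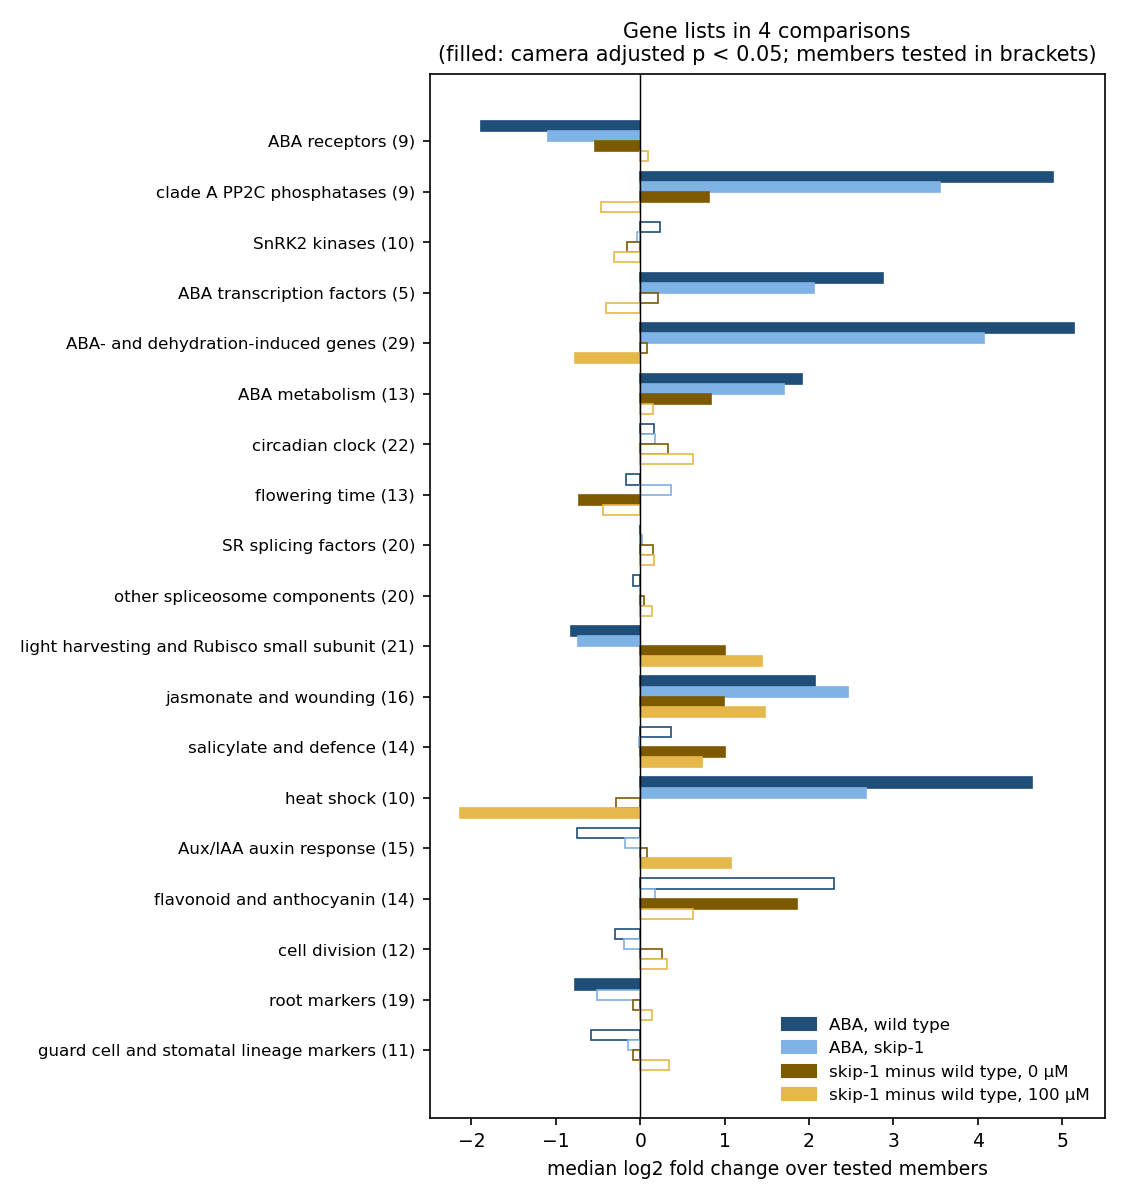
Median log2 fold change of 19 gene lists in 4 comparisons, 1 bar per list and comparison, filled where camera's adjusted p was under 0.05 and white otherwise. Dehydration-induced genes had medians of 5.14 and 4.07 for ABA in wild type and skip-1, and light-harvesting genes 1.00 and 1.44 for skip-1 without and with ABA.

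Skip-1 and wild type were also compared with ABA, to ask how the genotypes differed under the hormone. Of the 8 largest increases in skip-1, 5 were genes of the iron-deficiency response. IRT1 was 638-fold higher (114 to 25200), from 1 count in wild type. The iron-deficiency transcription factors bHLH38 (7.79 ± 0.70, adjusted p = 0.000922), bHLH39 (AT3G56980, 7.01 ± 0.72), BHLH100 (AT2G41240, 8.45 ± 1.41, adjusted p = 0.00765) and BHLH101 (AT5G04150, 6.68 ± 0.97) rose together. The level of bHLH38 was 0.328 ± 0.0952 in wild type and 74.4 ± 16.3 CPM in skip-1. That of BHLH100 was 0.099 ± 0.14 and 37.5 ± 5.5 CPM, so the size of its change is uncertain. Root markers, IRT1 included, did not pass as a list (3 higher and 3 lower of 19, 6 adjusted over the list alone; median 0.14, adjusted p = 0.263). AT1G13609 (8.17 ± 1.21) and the efflux carrier gene AT2G04070 (6.88 ± 0.88) rose too, and AT1G12030 (6.60 ± 1.4) lost its call without either wild type ABA library or skip-1 mock replicate 2 (adjusted p up to 0.0807). AT4G04410 (−6.18 ± 0.19) and MLP329 (−3.32 ± 0.18) were again lower. NEET (AT5G51720), for an iron-sulfur protein, changed by −3.59 ± 0.24 (adjusted p = 0.000125). The chaperone genes AT1G07400 (−3.42 ± 0.31) and HSP17.6II (AT5G12020, −3.09 ± 0.38), AT1G30250 (−3.38 ± 0.51) and the glycine-rich protein gene AT2G05510 (−3.23 ± 0.38) fell as well. THA1 (−3.10 ± 0.60) lost its call without either skip-1 ABA library (up to 0.0753). In all 6504 genes (31%) differed, 2855 higher and 3649 lower, and 2258 differed at least 2-fold. Without wild type ABA replicate 1 or 2, 3521 and 3937 genes were called, and without skip-1 ABA replicate 1 or 2, 3544 and 3794. Higher genes were 43.9% of the calls with TMM and 62.6% with library size alone, which put the median of all genes at 0.12. Of the genes called, 1192 were higher and 1236 lower in skip-1 both without and with ABA (298 and 365 if independent). Another 98 were called higher without and lower with ABA, and 25 the reverse.

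The ABA- and dehydration-induced and the heat shock lists were lower in skip-1 under ABA. Of 29 ABA- and dehydration-induced genes, 18 were lower and none higher (20 adjusted over the list alone; median −0.77, adjusted p = 4.58e-06, and adjusted p = 0.485 with an estimated correlation). LEA14 reached 1560 ± 182 CPM in wild type and 533 ± 29.3 CPM in skip-1 (−1.55 ± 0.14), LEA4-5 changed by −1.51 ± 0.24 and LTI30 by −0.89 ± 0.11. Of 10 heat shock genes, 8 were lower (8 adjusted over the list alone; median −2.13, adjusted p = 7.29e-06, and adjusted p = 0.14 with an estimated correlation), with HSP22 at −2.34 ± 0.23 and HSP101 at −1.79 ± 0.23. Of 5 ABA transcription factors, ABI5 (−1.77 ± 0.19) and ABF2 (−1.1 ± 0.16) were lower (3 adjusted over the list alone; median −0.41, adjusted p = 0.0635, and 0.0201 with the replicate block). Of 9 PP2C phosphatases, 4 were lower (4 adjusted over the list alone; median −0.47, adjusted p = 0.0743), and that list passed without skip-1 ABA replicate 2 (0.0145). Each of the 4 lost its call in some fit without 1 library. These fits were without wild type ABA replicate 2 for HAB1 (adjusted p = 0.0545), this or skip-1 ABA replicate 1 for HAB2 (up to 0.0782), either wild type ABA library or skip-1 ABA replicate 1 for ABI2 (up to 0.163), and any 1 library with ABA for HAI3 (up to 0.0988). Genes of ABA metabolism went both ways and did not pass as a list in the main fit (camera adjusted p = 0.0635). The list passed with the replicate block (0.0383) and in some fits without 1 library. BGLU18 stood at 1440 ± 277 in skip-1 against 175 ± 19.2 CPM in wild type (3.04 ± 0.15), and AAO3 was lower (−0.93).

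Other lists were higher in skip-1 under ABA. Of 21 light-harvesting and Rubisco genes, 16 were higher, with LHCB4.2 at 1.88 ± 0.12, and RBCS1B was lower (−0.53, lost without wild type ABA replicate 2 or skip-1 ABA replicate 2, up to 0.0883; 18 adjusted over the list alone; median 1.44, adjusted p = 1.23e-13, and adjusted p = 0.331 with an estimated correlation). The chloroplast share of counts was 0.743% and 0.831% in skip-1. Of 16 jasmonate and wounding genes, 10 were higher (12 adjusted over the list alone; median 1.48, adjusted p = 1.04e-07, and adjusted p = 0.331 with an estimated correlation), with JAZ6 at 2.3 ± 0.18 and OPR3 at 1.82. Of 14 salicylate and defence genes, 7 were higher (7 adjusted over the list alone; median 0.73, adjusted p = 0.00884, and adjusted p = 0.331 with an estimated correlation), with PR2 at 2.3 ± 0.38. Of 15 Aux/IAA genes, which are induced by auxin, IAA4 (1.07 ± 0.15), IAA14 (1.26) and IAA20 (at least 6.86-fold) were higher (3 adjusted over the list alone; median 1.07, also with IAA20 at its bound; adjusted p = 0.0199, and adjusted p = 0.485 with an estimated correlation). That call was lost without skip-1 ABA replicate 2 (0.0886) or wild type ABA replicate 1 (0.102). IAA14 lost its own without wild type ABA replicate 1 or skip-1 ABA replicate 1 (up to 0.088), and IAA20 without either wild type ABA library or skip-1 ABA replicate 2 (up to 0.112). FLC (−3.11 ± 0.45) and FT (−1.79) remained lower in skip-1, and RDM16 (1.05 ± 0.10) higher.

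**Figure D2:**
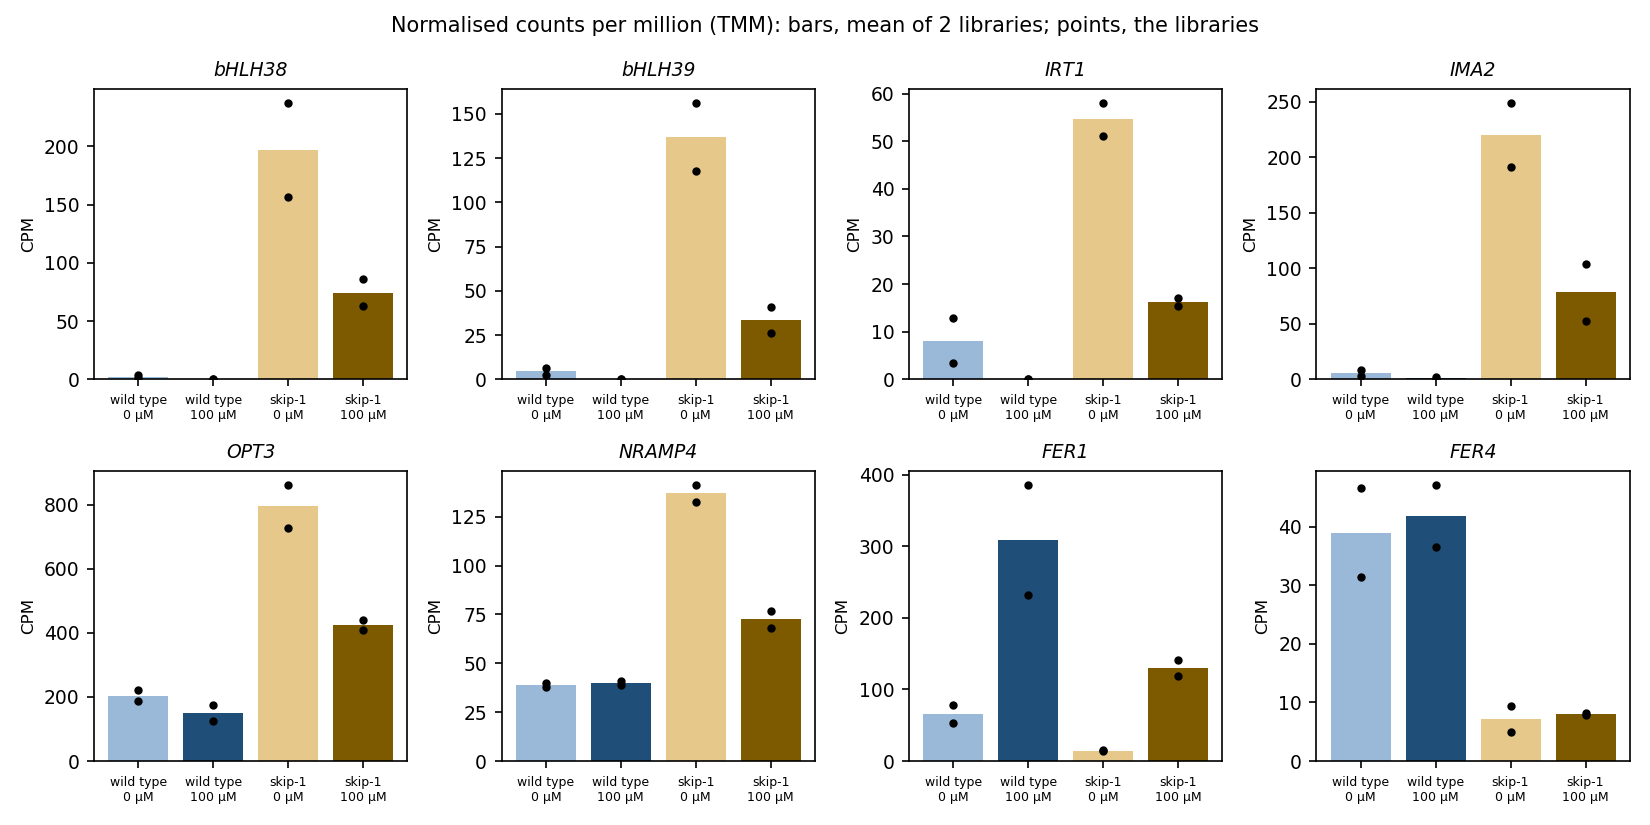
Levels of 8 genes of the iron-deficiency response in CPM, bars for the mean of 2 libraries and points for each library. bHLH38 stood at 197 in skip-1 and 2.13 in wild type without ABA, while the storage protein gene FER1 stood at 14.7 and 65.5.

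The interaction asked whether ABA acted differently in skip-1. RNS1 (AT2G02990), a ribonuclease gene, rose from 0.699 ± 0.187 to 221 ± 22.1 CPM in wild type and from 2.74 ± 0.585 to 45.1 ± 1.94 CPM in skip-1, a difference of −4.25 ± 0.27 (adjusted p = 0.00285). AT4G36700 (−6.36 ± 0.53, adjusted p = 0.00292) rose with ABA in wild type from 0.165 ± 0.119 to 8.89 ± 1.35 CPM and stood at 21 ± 7.42 and 13.4 ± 0.25 CPM in skip-1. AT5G45630, annotated as a senescence regulator, differed by −5.60 ± 0.59 (adjusted p = 0.00681). AT3G25190 (VTL5), for a vacuolar iron transporter, fell from 63.7 ± 4.17 to 4.55 ± 0.282 CPM in wild type and from 10.5 ± 1.92 to 3.41 ± 0.328 CPM in skip-1, a difference of 2.19 ± 0.23 (adjusted p = 0.00612). These 4 kept their calls without each of the 8 libraries. In all 644 genes (3.1%) were called, 168 with a higher and 476 with a lower effect in skip-1, and 416 differed at least 2-fold. The replicate block raised the count to 1357. Of the 644, 474 were raised by ABA in wild type, 463 of these with a lower effect in skip-1, and 147 were lowered, 144 with a higher effect. The class and the difference share the wild type libraries, so this choice of genes by itself favours a smaller response in skip-1. Without wild type mock replicate 1 or 2, 155 and 183 genes were called, without wild type ABA replicate 1 or 2, 121 and 319, and without skip-1 ABA replicate 1 or 2, 255 and 304. Higher effects were 26.1% of the calls with TMM and 55.5% with library size alone, which moved the median of all genes to 0.152.

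The other 12 genes chosen for the size of their difference each lost the call in some fit without 1 library. HSP17.4 (AT3G46230, −5.95 ± 0.94, 1 count in wild type without ABA), and the LEA gene AT3G02480 (−5.35 ± 0.53) lost it without either wild type mock library, with adjusted p up to 0.0732 and 0.0533. GASA3 (−6.88 ± 1.12, fitted against a group at 0) lost it without either wild type mock library or wild type ABA replicate 1 (up to 0.0853). MLO10 (AT5G65970, 2.27 ± 0.36) lost it without either wild type mock library or skip-1 ABA replicate 2 (up to 0.068), and AT1G51270 (2.47 ± 0.40) without these or wild type ABA replicate 1 (up to 0.0747). AT5G62280 (2.88 ± 0.41) lost it without any 1 wild type library (up to 0.102), and ATCSLA15 (AT4G13410, 4.34 ± 0.70) without any of those or skip-1 ABA replicate 2 (up to 0.11). For the RING protein gene AT1G24580 (−5.05 ± 0.72) it was any wild type library or skip-1 ABA replicate 1 (up to 0.11). SAG29 (AT5G13170, −4.50 ± 0.74) lost it without any 1 wild type library or either skip-1 ABA library (up to 0.144). AT3G20395 (4.04 ± 0.72) and XTH15 (3.20 ± 0.59) lost it without any 1 wild type library or either skip-1 mock library (up to 0.155 and 0.143), and XTH15 also with the replicate block (0.0775). AT2G15880 (2.2 ± 0.37) lost its call without wild type mock replicate 1, either wild type ABA library, skip-1 mock replicate 1 or skip-1 ABA replicate 1 (up to 0.11).

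The ABA response as a whole was smaller in skip-1. Over the 5489 genes raised by the mean ABA effect, the median change was 0.96 in wild type and 0.64 in skip-1, a median difference of −0.33 (fry in limma, adjusted p = 0.000114), and 77.1% of the genes changed less in skip-1. Over the 5109 lowered genes, the medians were −0.73 and −0.52, a median difference of 0.21 (adjusted p = 0.0045), with 71.6% changing less. The raised genes differed between genotypes by a median of 0.07 without ABA and −0.27 with ABA. Of the 463 genes raised in wild type and called for a lower effect in skip-1, 148 differed more between genotypes without ABA than with it (medians 0.35 without and −0.80 with ABA). These genes were chosen through their wild type values, which favours the signs of both medians.

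**Figure D3:**
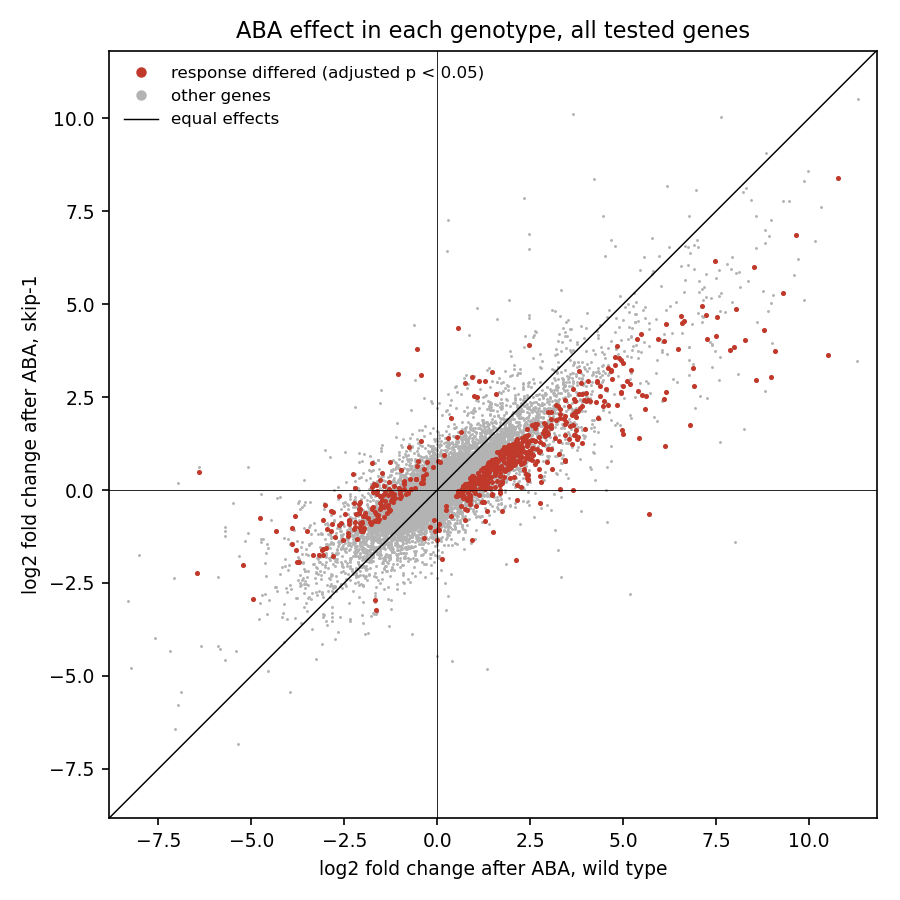
Log2 fold change with ABA of the tested genes in wild type (horizontal axis) and in skip-1 (vertical axis), 1 point per gene, red for the 644 genes whose response differed. The effects correlated at r = 0.832 across genes, which are not independent replicates.

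By list, the ABA- and dehydration-induced genes responded less in skip-1, with 6 of 29 called and all 6 lower (13 adjusted over the list alone; median −0.88, adjusted p = 7.1e-12, and adjusted p = 0.532 with an estimated correlation). HB7 rose from 26.4 ± 3.33 to 987 ± 7.27 CPM in wild type and from 75.8 ± 8.23 to 712 ± 33.3 CPM in skip-1 (−1.99 ± 0.17, adjusted p = 0.00292). GOLS2 (−1.91 ± 0.22) and RD22 (−1.59 ± 0.19), like HB7, kept their calls without each of the 8 libraries, while P5CS1 (−2.53 ± 0.37) lost it without either wild type mock library (up to 0.0883). GOLS2 reached 76.1 ± 2.3 CPM in wild type and 81.2 ± 7.61 CPM in skip-1 with ABA, from 3.9 ± 0.104 and 15.6 ± 3.63 CPM without it. Of 9 PP2C phosphatases, ABI2 (−1.34), HAB1 (−1.47) and HAB2 (−0.93) responded less (7 adjusted over the list alone; median −1.34, adjusted p = 5.47e-08, and adjusted p = 0.278 with an estimated correlation). Each of these 3 lost its call without wild type mock replicate 1 or wild type ABA replicate 1. Further losses came without wild type mock replicate 2 (ABI2, HAB2), wild type ABA replicate 2 and skip-1 mock replicate 1 (ABI2, HAB1), skip-1 mock replicate 2 (HAB1) and skip-1 ABA replicate 1 (HAB1, HAB2), with adjusted p up to 0.108 for ABI2, 0.102 for HAB1 and 0.0592 for HAB2. With the replicate block 6 of the 9 were called and the list passed by fry (adjusted p = 0.0468). Heat shock genes had a median of −1.56, with HSP17.4 called (5 adjusted over the list alone; adjusted p = 0.000214, and adjusted p = 0.235 with an estimated correlation), and were the only list past the threshold by fry without the block (adjusted p = 0.0153). With the block 5 of them were called, and 3 of the ABA transcription factors. ABA transcription factors had a median of −0.81 (3 adjusted over the list alone; adjusted p = 0.00848, and adjusted p = 0.571 with an estimated correlation), with ABF3 alone called (−1.23 ± 0.20). The list lost its call without skip-1 ABA replicate 1 (0.0775), skip-1 mock replicate 2 (0.0534), wild type ABA replicate 2 (0.0872) or wild type mock replicate 1 (0.0583). ABF3 lost its own without wild type mock replicate 1, either wild type ABA library or skip-1 ABA replicate 1 (up to 0.0908).

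The receptors, which ABA lowered, responded less as well, with PYL4 (2.01 ± 0.34) and PYL8 (1.03 ± 0.22) called of 9 (3 adjusted over the list alone; median 0.26, adjusted p = 0.00582, and adjusted p = 0.571 with an estimated correlation). PYL4 lost its call without any 1 wild type library or skip-1 mock replicate 1 (up to 0.124), and PYL8 kept it only without skip-1 mock replicate 2 (up to 0.154). Flavonoid and anthocyanin genes had a median of −1.60 with CHI called of 14 (−1.50 ± 0.19; 1 adjusted over the list alone; adjusted p = 0.00582, and adjusted p = 0.664 with an estimated correlation), and the list lost its call without skip-1 mock replicate 1 (0.951). Aux/IAA genes had a median of 0.94 with IAA4 called of 15 (1 adjusted over the list alone; adjusted p = 0.00588, and adjusted p = 0.643 with an estimated correlation). That list lost its call without skip-1 ABA replicate 2 (0.0644) or wild type ABA replicate 1 (0.0982), and IAA4 kept its own only without wild type ABA replicate 2 (up to 0.122). Guard cell and stomatal lineage markers had a median of 0.53 and no gene of 11 called (1 adjusted over the list alone; adjusted p = 0.0374, and adjusted p = 0.643 with an estimated correlation). With the replicate block FAMA was called (0.0344). The list's call was lost without skip-1 ABA replicate 1 (0.0901), skip-1 mock replicate 2 (0.365) or wild type ABA replicate 1 (0.0537) or 2 (0.0671). BGLU18 (1.56 ± 0.20) responded more in skip-1, a call lost without wild type ABA replicate 1 (0.0533). Genes of ABA metabolism passed as a list only with the replicate block (adjusted p = 0.292, and 0.0215 with the block, where 1 was higher and 4 lower). Jasmonate and wounding genes had a median of 0.48 and did not pass (adjusted p = 0.0634), although they did without skip-1 ABA replicate 1 (1.34e-05). Of their members VSP1 was called, with a higher effect in skip-1 (1.44 ± 0.28, adjusted p = 0.0394), and kept the call only without wild type ABA replicate 2 or skip-1 ABA replicate 1 (up to 0.125). In the fit with the block 3 were higher and 1 lower. No SR splicing factor or other spliceosome component was called by edgeR for the interaction (medians 0.02 and 0.11), while with the replicate block SR30 (0.0353) and RS40 (0.024) were.

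**Figure D4:**
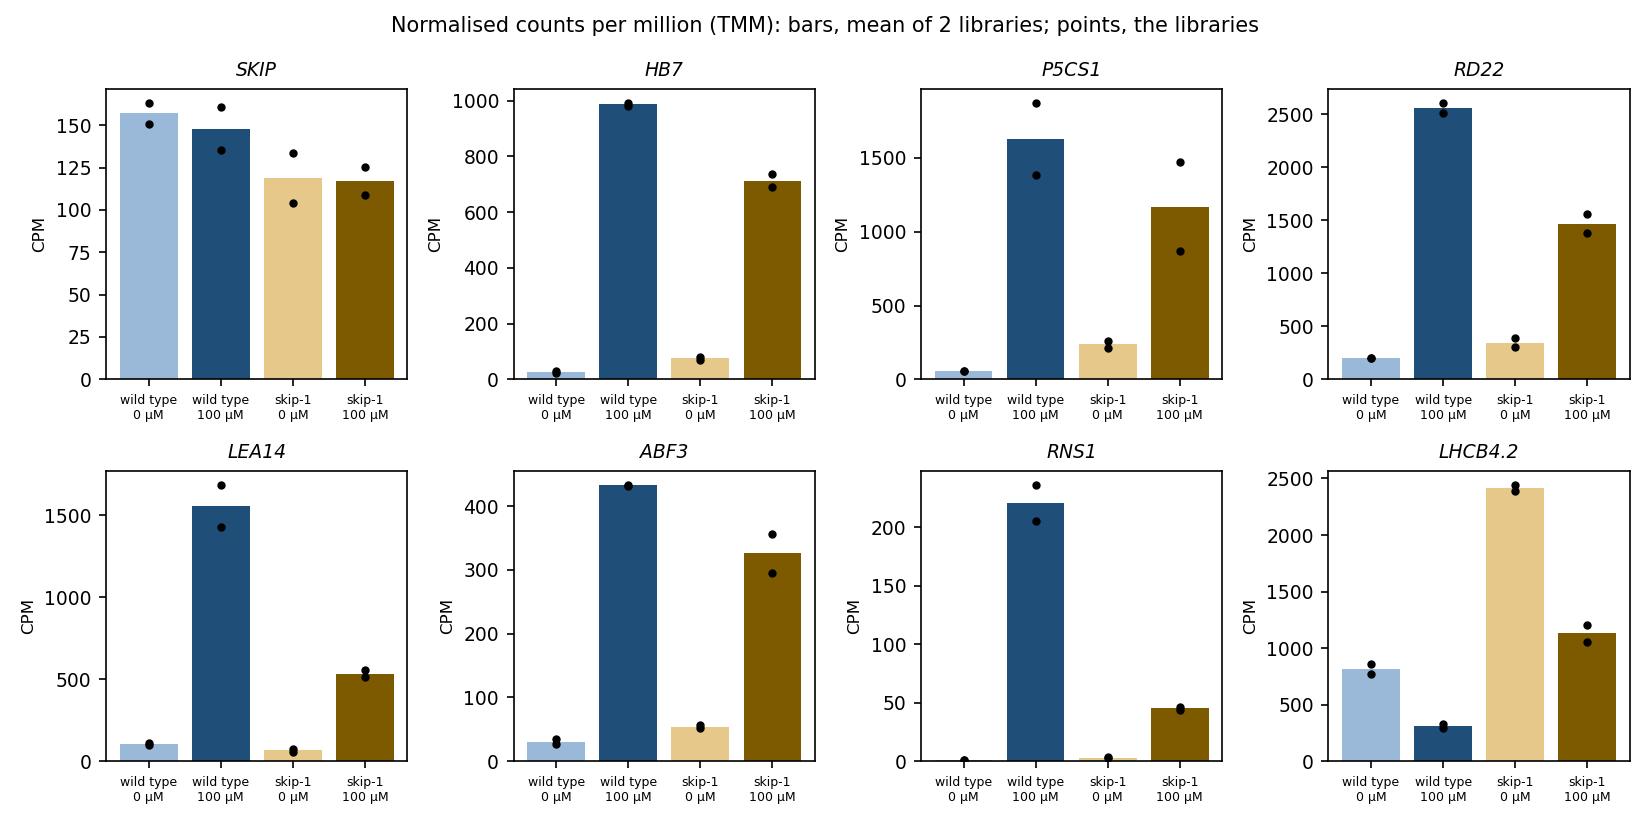
Levels of 8 genes in CPM, bars for the mean of 2 libraries and points for each library. With ABA, LEA14 reached 1560 in wild type and 533 in skip-1, RNS1 reached 221 and 45.1, and SKIP stood at 148 and 117.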

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

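The tests of explanations in this part were all chosen after the result they concern was seen. Each result here was taken up because a test of the difference itself showed ABA acting differently in skip-1 and in wild type.

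The response to ABA was smaller in skip-1, with 644 genes differing and a median difference of −0.33 over the genes that ABA raised and 0.21 over those it lowered. A scaling difference between libraries would shift both sets the same way, but over 3 scalings and without each library the lowered genes stayed at 0.17 or more and the raised genes at −0.24 or less. A changed starting level without ABA is argued against as the whole cause, since with ABA the genotypes still differed by −0.11 or further from 0 over the raised genes and 0.08 or more over the lowered genes, in each library pair and scaling, and by medians of −0.77 for ABA- and dehydration-induced and −2.13 for heat shock genes (list calls that did not hold with an estimated correlation, adjusted p = 0.485 and 0.14). A changed starting level may explain the median of the receptors (−0.54 without ABA, 0.09 with), but with ABA 2 of 9 were called higher and 2 lower. PYL4 (0.83, edgeR adjusted p = 0.0497, and 0.0809 with the replicate block) and PYL8 (0.62, adjusted p = 0.0189), both called for the interaction, were higher in skip-1 with ABA. Without ABA both had been lower in skip-1 (PYL4 −1.18, adjusted p = 0.00825, and PYL8 −0.41, adjusted p = 0.0919), so the difference changed sign. A changed starting level stays open for PP2C phosphatases (0.82 and −0.47) and ABA transcription factors (0.21 and −0.41), which differed with ABA short of the threshold (the factors passed it with the replicate block, 0.0201). GOLS2, HB7 and P5CS1 also started higher in skip-1. With ABA, GOLS2 (0.09, edgeR adjusted p = 0.652) and P5CS1 (−0.47, adjusted p = 0.194) did not differ past the threshold, while HB7 was lower in skip-1 (−0.47, adjusted p = 0.0191). A changed starting level may therefore explain the difference of GOLS2, and stays open for P5CS1. A lower effective ABA dose in skip-1 may explain it and stays open, because the jasmonate and wounding genes, raised in both genotypes, had a median difference of 0.48 whose adjusted p of 0.0634 missed the threshold and passed it without skip-1 ABA replicate 1 (1.34e-05). Of the 474 called genes that ABA raised in wild type, 11 responded more in skip-1, a number that false calls at the 0.05 threshold could give. Among them were BGLU18 (1.56 ± 0.20, edgeR adjusted p = 0.00942, lost only without wild type ABA replicate 1) and VSP1 (1.44, lost without most single libraries). BGLU18 was also higher in skip-1 without ABA (1.48). These genes therefore do not decide on a lower dose, and a weaker ABA signal or an altered breakdown of the hormone in the mutant was not tested.

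By list, the median ABA effect in skip-1 minus wild type was −0.88 for ABA- and dehydration-induced genes, −1.34 for PP2C phosphatases, −0.81 for ABA transcription factors, −1.56 for heat shock genes and −1.60 for flavonoid and anthocyanin genes. It was 0.26 for ABA receptors, 0.94 for Aux/IAA genes and 0.53 for guard cell and stomatal lineage markers. None of these 8 held with an estimated correlation, a version expected to have little power at 4 residual degrees of freedom. The estimates were 0.426 for ABA- and dehydration-induced genes, 0.29 for PP2C phosphatases, 0.47 for ABA transcription factors and 0.849 for flavonoid genes. They were 0.258 for receptors, 0.288 for Aux/IAA genes, 0.294 for guard cell markers and −0.068 for heat shock genes. Except for heat shock they lay above the preset of 0.01. If such correlations are real, the preset p-values of those lists are too small.

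Among single genes, the ABA effect was lower in skip-1 by the fit for GASA3 (−6.88), AT4G36700 (−6.36), HSP17.4 (−5.95), AT5G45630 (−5.60), AT3G02480 (−5.35), AT1G24580 (−5.05), SAG29 (−4.50) and RNS1 (−4.25). It was higher for ATCSLA15 (4.34), AT3G20395 (4.04), XTH15 (3.2), AT5G62280 (2.88), AT1G51270 (2.47), MLO10 (2.27), AT2G15880 (2.2) and AT3G25190 (2.19). The fitted values of GASA3 and HSP17.4 depend on the prior count, since wild type without ABA had 0 and 1 counts.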

How the results depend on the processing

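All alternatives reported here were planned. With an estimated correlation between genes, 4 lists were called for ABA in wild type, 4 for ABA in skip-1 and 0 in each of the other 3 comparisons, where camera with its preset correlation called 9, 8, 8, 6 and 8. That version is expected to have little power here, while the preset version gives p-values that are too small for lists of more strongly correlated genes. For ABA in wild type, camera with an estimated correlation gave adjusted p = 0.0289 for ABA- and dehydration-induced genes, although all 29 rose with a median of 5.14. With fry, 1 list passed for the interaction, a test of another question. A minimum of 2-fold left 4321 genes for ABA in wild type, 2516 for ABA in skip-1, 1584 and 2258 for skip-1 without and with ABA, and 416 for the interaction, as a stricter rule must.

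The interaction count of 644 moved most. It was 1201 with the DESeq2 Wald test, 423 with limma on log2 FPKM with a pseudocount of 0.1, and 218 with limma on every gene with any FPKM, and the cause was not tested. In the simulated interaction DESeq2 called more genes than edgeR, with 33 false calls among 122 against 7 among 76. It recovered 34.3% of 2-fold differences there, against 13.4% for edgeR. With DESeq2 size factors it was 581, with library size alone 535, without a count filter 746 and with at least 10 counts in every library 617.

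The replicate number as a block gave 1357 genes for the interaction, 636 of them among the 644, and the cause was not tested. Apart from the calls given beside their results, the block changed that of no other gene or list in a comparison for which the report names it.

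Without 1 library, the lone library of its group being assumed to vary like those of the other groups, 6585 to 9368 genes were called for ABA in wild type and 3532 to 5625 for ABA in skip-1. The range was 1383 to 3785 for skip-1 without ABA, lowest without wild type mock replicate 2, and 3521 to 6851 for skip-1 with ABA, lowest without wild type ABA replicate 1. For the interaction it was 121 to 608, lowest without wild type ABA replicate 1. Lists called numbered 8 to 10, 8 to 10, 8 to 9, 6 to 9 and 6 to 10 in the same order. The median difference in ABA response ran from −0.40 to −0.26 for raised genes and from 0.17 to 0.32 for lowered genes, and fry stayed under 0.05 in each.

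Of 234 results for SKIP, the largest changes and the members chosen by rule from lists that passed, 207 were past the threshold. Leaving out 1 library ended 43 of these calls in some fit, and the block ended 2. Of the 478 other calls of list members and iron genes, 225 ended in some fit without 1 library. The DESeq2 Wald test added 9 calls, the block 10 and DESeq2 size factors 1, and no direction changed under these alternatives. Since fits without 1 library have less power, calls can end in them without much change in the effect.

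At this depth and with 2 libraries per group, small effects were recovered least in the interaction, with 13.4% of simulated 2-fold and 89.4% of 4-fold differences, against 58.2% and 97% for ABA in wild type. Neither depth nor the number of libraries was varied, and the simulation changed few genes, unlike the comparisons in which many were called.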

Other observations

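The iron-deficiency list and the split of genes by intron number were chosen after results had been seen. The tests on the intron split, and that on 17 induced iron genes, were fixed before the values they measure were looked at. The full sets of 26 induced and 5 repressed iron genes also hold members seen before, such as bHLH38, IRT1, FER4 and VTL5, so their counts and medians rest partly on values already known. The iron genes named here lie outside the rule for named genes and were chosen after their values were seen.

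Genes of the iron-deficiency response formed a set that none of the planned lists covered. Without ABA, 22 of 26 genes induced by iron deficiency were higher in skip-1 and only BTSL2, for an iron-sensing ligase, was lower (−0.96 ± 0.17). OPT3, an iron transporter gene of the phloem, went from 204 ± 24.2 to 795 ± 95.4 CPM (1.96 ± 0.17, edgeR adjusted p = 0.000592). NRAMP4, which releases iron from the vacuole, rose by 1.81 ± 0.10 (adjusted p = 7.51e-05), NAS2 by 4.0 ± 0.27 and the regulator gene PYE by 1.89 ± 0.19. The genes FIT (−0.88, adjusted p = 0.15) and NAS1 (−0.32, adjusted p = 0.242) did not change past the threshold. Of 5 genes repressed by iron deficiency 4 were lower, the ferritin genes FER1 (−2.16 ± 0.29), FER3 (−1.31 ± 0.15) and FER4 (−2.45 ± 0.32) and the vacuolar transporter gene VTL5 (−2.60 ± 0.15). With ABA, 21 of the 26 induced genes were higher in skip-1 (median 1.87) and 3 of the 5 repressed genes were lower (median −1.25). The induced genes BTSL2 (−0.59 ± 0.17, adjusted p = 0.0324) and F6H1 (−0.77 ± 0.18, adjusted p = 0.0126) were lower with ABA. Both lost that call without wild type ABA replicate 2 or either skip-1 ABA library (up to 0.167 and 0.0779). F6H1 had been higher without ABA (1.02 ± 0.18), a call lost without wild type mock replicate 2 (0.0516).

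An iron-deficiency response in skip-1 is a candidate explanation. The 17 induced genes whose values had not been looked at had a median of 1.84 without ABA, 13 of them higher and 1 lower, with camera at 3.49e-15 before and 1.74e-14 after adjustment, and 0.132 after adjustment with an estimated correlation. Without 1 library their median ran from 1.44 to 2.07. A larger share of root tissue in skip-1 is argued against, since the upper quartile of 18 root markers other than IRT1 was 0.30 (median −0.12). That is below the iron list's median of 2.09, which includes genes seen before, and below the 1.84 of the 17 genes not looked at. Iron content was not measured, and a change in iron supply, sensing or transport in the mutant stays open.

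Genes without introns were lower in skip-1 with ABA, with a median of −0.30 over 3166 genes, 7.9% called higher and 25.1% lower, while genes with 2 or more introns had medians from 0 to 0.04. Without ABA the median of intronless genes was −0.10, with 7.5% called higher and 10.5% lower, and camera did not pass (adjusted p = 0.128). Without 1 library that median ran from −0.06 (without skip-1 mock replicate 1) to −0.13 (without skip-1 mock replicate 2). Genes with 11 or more introns were also lower without ABA, with a median of −0.08, 6% called higher and 15.6% lower, so a shift downward was not particular to intronless genes. The ABA effect in skip-1 rose with intron number, from −0.25 without introns to 0.14 with 11 or more, and in wild type it ran from −0.08 to 0.04. For the difference between these effects over intronless genes, camera gave adjusted p = 0.0152, and 0.297 with an estimated correlation. Camera passed for intronless genes in skip-1 against wild type with ABA (adjusted p = 0.00083) and not with an estimated correlation (adjusted p = 0.297). Within 10 bins of exonic length the difference between intronless and other genes was −0.27, within bins of expression −0.39 and within bins of GC content −0.30. Among 5792 genes whose mean ABA effect had an unadjusted p above 0.2, which does not show that they had none, it was −0.26, against −0.30 over all genes without bins. With the replicate block these differences were the same.

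Those values argue against gene length, expression level, GC content and the smaller response of ABA-raised genes as the whole cause of the difference of −0.30. Since SKIP acts in splicing, a change in how intron-containing transcripts are made or kept may be involved, but normalised counts are relative. Lower intronless and higher intron-containing transcripts cannot be separated by them, and splicing was not measured. How reads in retained introns were counted is not given in the sources used here.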
